A study of Drosophila melanogaster with 9 samples.

How the data were processed

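Gene expression was measured by stranded mRNA sequencing in retinas with optic lobes of Drosophila melanogaster pupae at 48 h after puparium formation (APF), raised at 25 °C. Per the labels' protocols, libraries were made from 250 ng of total RNA. The 9 samples form 3 groups of 3 biological replicates. Control animals carried the lGMR-GAL4 driver alone. The other groups carried the same driver with either a Blimp-1 RNAi construct or a UAS Blimp-1 construct, here called RNAi and overexpression. The control genotype, as labelled, holds no UAS insert. The labels name retinas and optic lobes together for each sample, so the tissues were not compared.

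Per the submitters' processing notes, the tools included STAR 2.6.1d, Picard 2.18.20, Subread 1.6.3, bedtools 2.26.0 and DESeq2, with the genome build dm6; their settings and roles are not given in the sources used here. The authors deposited 4 tables, of genes lower or higher in RNAi and lower or higher in overexpression. Each row holds normalized read counts per library, a signal that the authors scaled by 1 factor per library, per the values in the deposited tables. Each row also holds a log2 fold change and an adjusted p-value of the authors, and a function and a stage of peak expression as deposited text. The RNAi tables hold marks for Blimp-1 and Slbo sites too; how sites, functions and stages were assigned is not given in the sources used here. The deposited log2 fold changes were control over altered genotype and were turned around, so that a positive value here means higher in the altered genotype. Within rounding, they lay no farther from 0 than the ratio of group means in 1069 of 1069 entries with reads in both groups. The tables hold only genes with an absolute log2 fold change of at least 1 and an adjusted p under 0.05. The number of genes tested is therefore unknown, no enrichment against tested genes was computed, and a gene listed in 1 comparison has no values in the other altered genotype. For the same reason the fixed gene lists could not be adjusted over the list alone.

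Low values showed that each library's normalized counts were whole multiples of 1 step. Whole reads were recovered for 100% of nonzero values in each of the 9 libraries, within 0.02 reads. The steps were the same in all tables, so values of the 9 libraries share a scale. Recovered reads in listed genes ranged from 954516 to 2306340 per library; total depth is unknown. The SDs given hold both counting error and the spread between animals.

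Means, SDs and folds were computed from the normalized counts of 3 against 3 libraries, without a pseudocount. The standard error of a log2 ratio was taken from both groups' SDs. Where 1 group had no read, the fold was computed against a floor of 3 reads over the group and is a lower bound. Gene symbols and coordinates came from the Ensembl annotation of BDGP6.54, whose coordinates are those of dm6. Of 904 distinct listed genes, 874 had a FlyBase identifier and 867 were placed. In 1 table, 2 symbols had been altered by a text replacement (ZnT33D and Myo31DF) and were restored by identifier. Another 6 genes in both comparisons were matched by symbol although an identifier was missing from at least 1 table.

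Before the data were examined, 28 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took Blimp-1, per table the 8 largest changes among genes with a mean of at least 20 normalized counts and the 4 smallest adjusted p-values, the 6 genes listed in both comparisons with the largest summed change for each of same and opposite direction, and up to 4 members per list and comparison. Other genes named as further list members, as members of a function class or in runs of neighbours were chosen after their values were seen. The list of noncoding RNA genes was taken by symbol, and some of its members are annotated as pseudogenes or protein-coding genes. Direction of a list was tested with Fisher's exact test, two-sided, against the other listed genes, for lists with at least 3 listed members. Benjamini-Hochberg adjustment was over these lists. Sizes of changes and correlations across genes were tested with 100000 permutations. Permutation tests were two-sided unless said otherwise. Tests of function, stage and site annotation were chosen after the tables were seen.

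A count test was added after the data were seen. The recovered reads of listed genes were fitted with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with the recovered size factors. It runs on genes already selected by the authors, so its p-values are no independent evidence. Tested on simulated data, it recovered 83% of 2-fold and 97% of 4-fold changes among the 373 genes of RNAi, with 3 of 173 unchanged genes called. For the 710 genes of overexpression these values were 64% and 95%, with 9 of 510 unchanged genes called. The list test was run on 400 random lists per setting, and on lists in which lower genes were 5 times as likely to be drawn, before adjustment. Among the 373 genes of RNAi it called 2.5% of unchanged and 49.2% of shifted lists of 10 members, and 3.8% and 0.0% of lists of 5. Among the 710 genes of overexpression it called 3.2% and 71.8% of lists of 10 members, and 2.5% and 42.8% of lists of 5. Small lists could thus miss a shift of this size toward lower genes. Lists shifted toward higher genes were not simulated. No pair of replicates agreed within sampling noise; the chi-square per gene was at least 17.8. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

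Alternatives were a stricter adjusted p (0.01 or 0.001), a mean of at least 50 normalized counts, leaving out each library, a replicate block, lists without genes shared between lists, and 1 gene per cuticle protein cluster. Refits with other size factors or without a filter need counts of all genes and were not run.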

Results

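Retinas with optic lobes were profiled at 48 h APF to ask how gene expression changes when Blimp-1 is lost or gained under lGMR-GAL4, a driver active in the developing eye. Blimp-1 encodes a zinc finger transcriptional repressor induced by the moulting hormone ecdysone. RNAi and overexpression were each compared with the same 3 control libraries, with 3 biological replicates per group. In the control libraries, 1189615 to 2306340 reads fell in the 904 listed genes. The range was 954516 to 1318419 reads over 373 genes in RNAi and 1322202 to 1918155 reads over 710 genes in overexpression. Values are normalized counts as mean ± SD with n = 3, and folds are ratios of these means.

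Blimp-1 (FBgn0035625, dm6 3L 5630983 to 5652094) was 20.3-fold higher in overexpression, at 16999 ± 6980 normalized counts against 836.7 ± 76.7 in control (SD, n = 3). Its adjusted p in the authors' deposited table was 2.87e-38. The 3 overexpression libraries held 9467, 18277 and 23252 normalized counts, all above the control libraries. Blimp-1 had no entry in the RNAi tables, so its level after RNAi is not known from the values used here. No fall of Blimp-1 was thus listed at an absolute log2 fold change of at least 1 and an adjusted p under 0.05. The nuclear receptor gene ftz-f1, which Blimp-1 is known to repress, was 8.57-fold higher in RNAi, at 46.6 ± 6.1 against 5.44 ± 1.81 normalized counts (SD, n = 3). It had no entry in the overexpression tables, which says little about a fall there, given its few normalized counts in control.

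**Figure D1:**
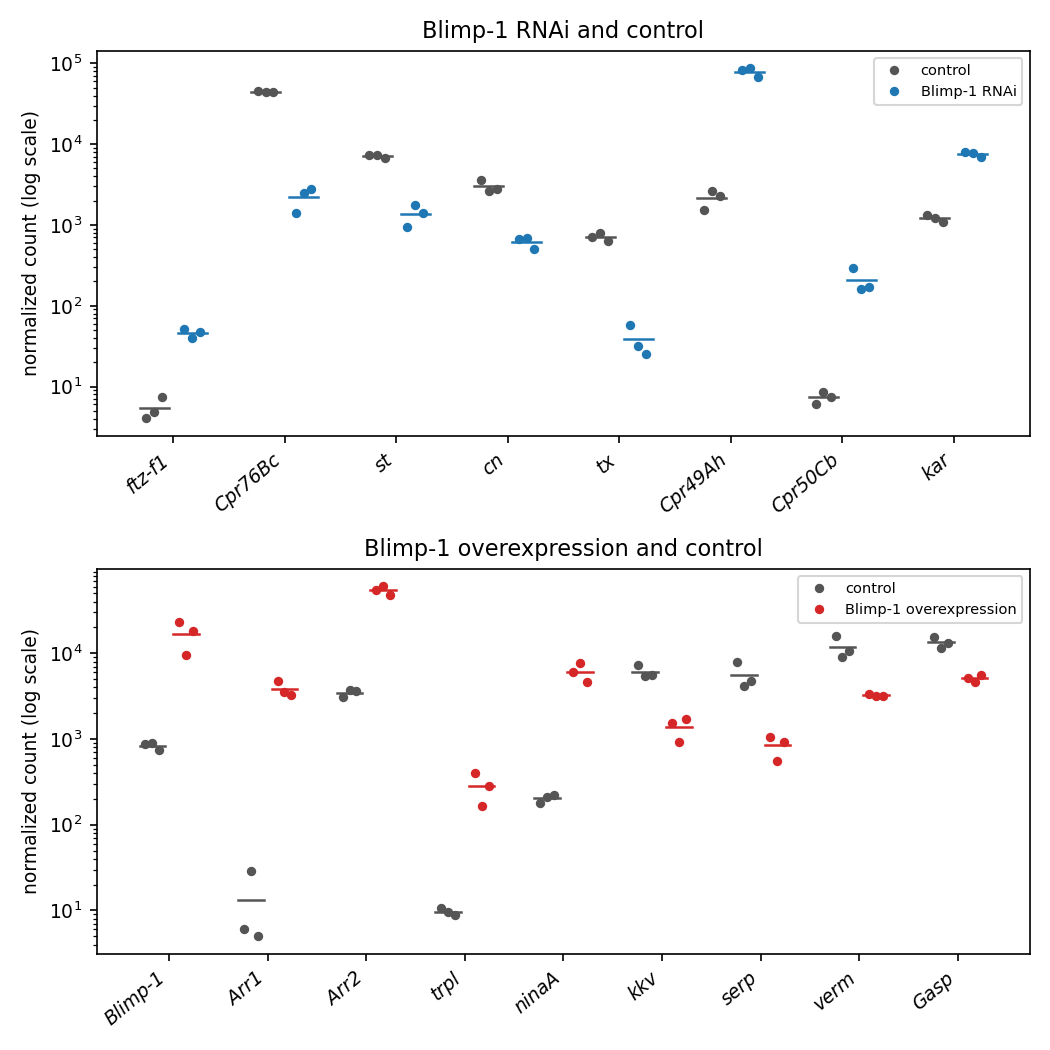
Normalized counts per library (log axis) of selected genes in RNAi with control (top) and overexpression with control (bottom); points are the 3 libraries of a group and lines their means. In each gene shown the 3 libraries of the altered genotype lie on 1 side of the 3 control libraries, as for Blimp-1 at 9467 to 23252 against 748.5 to 887.7.

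Blimp-1 RNAi lowered 189 genes and raised 184 in the authors' deposited table. Among genes with a mean of at least 20 normalized counts, the largest fall was in CG14624, a gene of unknown function on the X chromosome (dm6 1206737 to 1207555). It went from 24511 ± 8447 normalized counts in control to 58.4 ± 15.6 in RNAi, 419.8-fold lower (SD, n = 3). CG14857 was 35.8-fold lower, from 45.8 ± 3.3 to 1.28 ± 0.39, with 4 reads in all RNAi libraries (SD, n = 3). CG14866 was 30.1-fold lower, from 10439 ± 369 to 346.9 ± 11.6, and the cuticle protein gene Cpr76Bc was 20.2-fold lower, from 44656 ± 951 to 2209 ± 715 (SD, n = 3). Adjusted p-values in the authors' deposited table were 3.06e-214 for CG14624, 4.77e-248 for CG14866 and 2.02e-73 for Cpr76Bc. Other large falls were in CG15506 (20.1-fold), CG34382 (19.3-fold) and tx, encoding a transcription factor (18.6-fold). Among genes that rose, CG6347, now named CtsL2, was 100.9-fold higher, from 25.9 ± 6.8 to 2609 ± 657 (SD, n = 3). CG8927 was 76.0-fold and CG42367 52.5-fold higher, both annotated by the authors as cuticle. CG13675, CG32037 and CG14752 were 93.3-, 67.0- and 58.4-fold higher. CG42367 reached 140870 ± 35567 normalized counts from 2682 ± 469 (SD, n = 3). Its adjusted p was 2.31e-155 in the authors' deposited table.

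Cuticle and chitin genes went both ways in RNAi. Of 8 listed cuticle protein genes 5 were higher, with Cpr49Ah 37.0-fold, Cpr50Cb 28.2-fold and Cpr92F 16.4-fold higher, and 3 were lower (Fisher's exact test, adjusted p = 1). Of 9 listed chitin genes 7 were higher, among them reb, which acts in chitin deposition, 15.0-fold, and Peritrophin-A, 5.90-fold (Fisher's exact test, p = 0.101, adjusted p = 0.655 over 11 lists). The 2 lower chitin genes were obst-E and obst-B. Eye pigment genes also split. Of these, st, cn and cd, for a transporter, kynurenine 3-monooxygenase and a pigment enzyme, were 5.22-, 4.87- and 3.08-fold lower. In contrast, kar was 6.31-fold and Pu 2.25-fold higher (adjusted p = 1 for the list). Of 5 listed ecdysone pathway genes, ftz-f1, vri and Cyp18a1, which encodes an ecdysone-inactivating enzyme, were higher and ImpL1 and ImpL2 lower (adjusted p = 1). Of 10 listed detoxification genes 6 were lower, led by Cyp6a20, 9.57-fold, and 4 higher (adjusted p = 1). The list of noncoding RNA genes, taken by symbol, held 8 lower and 4 higher (adjusted p = 1). By annotation 1 of the lower and 2 of the higher were pseudogenes, and 1 of the higher, CR45273, a protein-coding gene. In addition, the 3 listed odorant binding genes were all higher (Fisher's exact test, p = 0.119, adjusted p = 0.655). All 3 higher is the most extreme outcome in that direction, so 3 genes could not pass toward higher. No list passed the adjusted threshold for direction. In the simulation, lists of 5 members shifted toward lower genes were called in 0.0% of draws before adjustment. For lists of 5 or fewer members, not passing toward lower genes therefore says little about their direction. Zona pellucida domain proteins had cyr and dyl lower and qsm higher, tanning genes 2 lower and 2 higher, and immune genes 2 lower and 1 higher (adjusted p = 1 each). Among phototransduction genes chp and pinta were lower and ninaD higher (adjusted p = 1). Lists with fewer than 3 listed members had no test. In these h, egr, Tsp42Ed, LysX, RpS5b and Zasp52 were higher, of the cone and pigment cell, cell death, bristle, gut, ribosomal and muscle lists. The hemocyte gene Ppn (3.27-fold) and the muscle gene sls were lower. The lists of photoreceptor identity, glia, Notch pathway, synapse and fat body had no listed gene in RNAi.

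By the authors' function annotation, cytoskeletal genes were mostly lower in RNAi. Of these genes 18 were lower and 2 higher, including among the lower CG3339 (8.16-fold), Root, whose product forms the ciliary rootlet (4.39-fold), and sls, a titin-like muscle gene (3.18-fold). The other listed genes held 171 lower and 182 higher (Fisher's exact test, p = 0.000292, adjusted p = 0.00263 over 9 classes). The cuticle class held 18 higher and 7 lower (Fisher's exact test, p = 0.0224, adjusted p = 0.101). No other class passed. Classes were those of the comparison's own tables, and 39 of the 179 genes listed in both comparisons had a different class for overexpression. Among lower cytoskeletal genes, Strn-Mlck, CG2157 and CG5104 were such cases, while Root, qua, Myo31DF, Frl and CG3339 kept their class. Marks for Blimp-1 sites stood beside 41.3% of the 189 lower and 43.5% of the 184 higher genes (Fisher's exact test, p = 0.676), with an odds ratio of 0.914 (95% interval 0.593 to 1.41). Marks for sites of Slbo, another transcription factor, stood beside 31.2% of lower and 37.5% of higher genes (Fisher's exact test, p = 0.23). Genes with a mark for 1 factor more often carried the other, at 89 genes with both (Fisher's exact test, odds ratio 5.79, p = 1.94e-14).

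Genes that the authors annotated as peaking at the 2 d pupal stage, the age of the samples, were mostly lower in RNAi. Of 86 lower genes with a stage entry, 59 (68.6%) peaked at 2 d, against 34 of 132 higher genes (25.8%; Fisher's exact test, p = 4.19e-10, odds ratio 6.24, 95% interval 3.32 to 12). Genes that peak earlier were 48 higher and 5 lower, and genes that peak later 50 higher and 22 lower. Stage cells were blank for 103 lower and 52 higher genes. Stage entries differed between comparisons in 37 of the 179 genes listed in both, mostly because a cell was blank. Lower genes blank for RNAi had earlier stages for overexpression in CG4115, cv-c, Myo31DF, fj, Frl, CAH2 and Skp2. Later stages stood beside CG43078, ImpL3, CG10211, CG34460 and CG4325, and 2 d beside Clic and pip. Higher genes with such blanks had only earlier or later stages there. The shares above use the RNAi entries alone.

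Blimp-1 overexpression raised 514 genes and lowered 196 in the authors' deposited table. Arr1, which encodes a photoreceptor arrestin, was 289.4-fold higher, from 13.3 ± 13.5 to 3842 ± 755 normalized counts (SD, n = 3). Hey, a basic helix-loop-helix gene, rose 247.3-fold, from 1.6 ± 0.8 to 394.9 ± 139.9 (SD, n = 3), with 5 reads in all control libraries. Pu, which encodes GTP cyclohydrolase and serves pteridine pigment synthesis, rose 61.6-fold, from 536.1 ± 29.4 to 33029 ± 5161 (SD, n = 3). The control libraries held 6.0, 28.8 and 5.0 normalized counts of Arr1, and without control replicate 2 its fold was 696.0. Adjusted p-values in the authors' deposited table were 4.74e-63 for Arr1, 3.49e-25 for Hey and 1.69e-173 for Pu. CG7214, Ser7, Osi19 and CG13841 were 193.8-, 187-, 163.8- and 174.4-fold higher. The folds were 379.9 for CG13841 without control replicate 2 and 248.6 for Osi19 without control replicate 3. Among genes with a mean of at least 20 normalized counts, the largest fall was in the tetraspanin gene Tsp47F, 91.9-fold lower, from 11603 ± 744 to 126.3 ± 108.3 (SD, n = 3), where the libraries of the altered group spread widely, and 173.3-fold lower without overexpression replicate 2. Slc45-1 was 27.2-fold lower (5007 ± 364 to 184.3 ± 35.3) and CG7080 21.4-fold lower (4435 ± 752 to 207.3 ± 31.5; SD, n = 3).

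Of 14 listed phototransduction genes 11 were higher in overexpression, while the other listed genes held 503 higher and 193 lower (Fisher's exact test, p = 0.768, adjusted p = 1 over 15 lists). Beside Arr1, the arrestin gene Arr2 rose 15.8-fold to 54505 ± 6241 normalized counts (SD, n = 3). The rhodopsin chaperone gene ninaA rose 30.1-fold and the channel gene trpl 29.4-fold. The scaffold gene inaD fell 2.80-fold and eys and prom fell 3.40- and 2.72-fold. Of 5 listed eye pigment genes 4 were higher, namely Pu, kar (10.4-fold), w (3.21-fold) and bw (2.31-fold), and cd was 2.38-fold lower (adjusted p = 1). The w gene is a common marker of transgenes, so its level can include marker transcripts. Of 6 listed tanning genes 5 were higher, such as t (8.99-fold) and e (7.27-fold), and yellow-e was 4.88-fold lower (adjusted p = 1).

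Of 12 listed chitin genes 8 were lower in overexpression: the deacetylase genes serp (6.66-fold), verm (3.64-fold) and Cda5 (4.02-fold), the chitin synthase gene kkv (4.40-fold), Cht7, Gasp, obst-A and exp. ChLD3, Cht10, Idgf6 and reb were higher. The other listed genes held 188 lower and 510 higher, and the difference passed before adjustment (Fisher's exact test, p = 0.00509) but not after it (adjusted p = 0.0764). Among genes with a mean of at least 50 normalized counts, the adjusted p was 0.0363, and over all alternatives it ranged from 0.0363 to 0.0764. Of 12 listed cuticle protein genes 8 were higher, such as Cpr50Cb (108-fold) and Cpr47Ef (53.1-fold, or 35.4- and 101.2-fold without control replicate 2 or 3), and 4 lower, such as Cpr49Ae (14.8-fold; adjusted p = 1). Of 22 detoxification genes 20 were higher, such as Cyp6a16 (28.3-fold) and Cyp4s3 (23.9-fold; Fisher's exact test, p = 0.0528, adjusted p = 0.396).

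Markers of other cell types were also among the listed genes. With most listed genes higher, even 4 of 4 higher gave p = 0.58 (Fisher's exact test), so lists of 4 could not pass toward higher. The 4 listed glial genes, e (also a tanning gene), wrapper, Tret1-1 and nrv2, and the 4 listed hemocyte genes, srp, NimC3, NimC4 and NimC2, were all higher in overexpression, by 2.32- to 7.27-fold and 3.39- to 5.72-fold (adjusted p = 0.967 each). Of 7 synaptic genes Hdc (8.71-fold), nAChRbeta3 and CarT were higher and Rim and 3 acetylcholine receptor subunit genes lower (Fisher's exact test, p = 0.0961, adjusted p = 0.48). Of 9 immune genes 8 were higher, 6 of them serpin genes, and the serpin gene Spn85F was lower (adjusted p = 0.967). Ecdysone pathway genes held ImpL1 (13.2-fold), vri, ImpE1 and ImpE3 higher and Hr4 (3.05-fold), Eip74EF and Eip78C lower (adjusted p = 0.967). No listed gene belonged to the lists of neuroblast and cell cycle genes, optic lobe transcription factors, cell surface recognition, heat shock or sex in either comparison. The 4 odorant binding or receptor genes were all higher (adjusted p = 0.967), zona pellucida domain genes held 3 higher and 1 lower and bristle genes 3 higher and 1 lower (adjusted p = 1 each), and the list of noncoding RNA genes, taken by symbol, held 24 higher and 11 lower (adjusted p = 0.967). By annotation 7 of the lower were noncoding, 2 pseudogenes and 1 a protein-coding gene, while 1 lower and all 24 higher had no identifier in the overexpression tables. Of these, CR44370 and CR44465 are noncoding by the identifiers in the RNAi tables. The bristle list's 3 higher members were the tetraspanin genes Tsp42Ej, Tsp42Ek and Tsp42El, and its lower member was jv; how reads shared by such neighbouring copies were counted is not given in the sources used here. The Notch pathway list had E(spl)m2-BFM and E(spl)m3-HLH higher. Photoreceptor identity had boss higher (2.37-fold) and salm lower (2.52-fold). Zasp66 (12.5-fold, or 28.6-fold without control replicate 2), egr, Mal-B2, RpS5b and Tsf1 were higher, the only listed members of the muscle, cell death, gut, ribosomal and fat body lists. The cone and pigment cell list had no listed gene in overexpression. Lists with fewer than 3 listed members had no test.

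By the authors' function annotation, transporter genes held 46 higher and 6 lower in overexpression (Fisher's exact test, p = 0.00582, adjusted p = 0.0262). Transcription factor genes held 14 higher and 15 lower (Fisher's exact test, p = 0.00514, adjusted p = 0.0262), and cell surface genes 47 higher and 32 lower (Fisher's exact test, p = 0.0107, adjusted p = 0.032). Enzyme genes held 195 higher and 56 lower (Fisher's exact test, p = 0.0223, adjusted p = 0.0502). Classes were those of the overexpression tables, with the differences between tables given above. Of genes that peak at 2 d, 61 were lower and 60 higher. They made up 49.2% of the 124 lower and 17.8% of the 337 higher genes with a stage entry (Fisher's exact test, p = 7.58e-11, odds ratio 4.45, 95% interval 2.78 to 7.17). Genes that peak earlier made up 24.2% of the lower and 36.5% of the higher genes, and genes that peak later 26.6% and 45.7%.

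**Figure D2:**
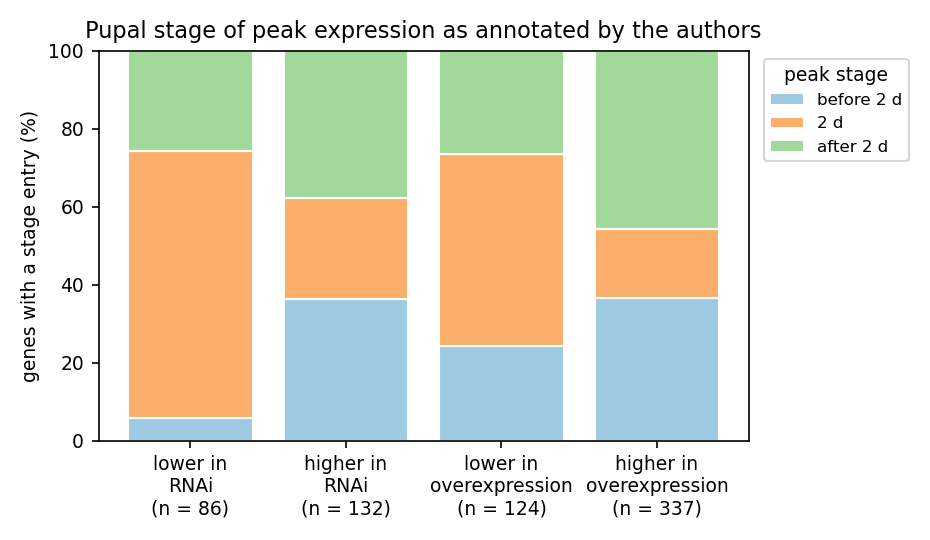
Percent of listed genes with a stage entry that peak before, at or after the 2 d pupal stage, as annotated by the authors, for genes lower and higher in each comparison. Genes that peak at 2 d made up 68.6% and 49.2% of lower genes and 25.8% and 17.8% of higher genes in RNAi and overexpression. Stages were those of each comparison's own tables, where many cells were blank and some entries differed between comparisons.

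Among listed genes, higher ones changed more than lower ones in both comparisons. The tests shuffled directions over genes, which are not independent replicates, and changes under 1 on the log2 scale were not listed. In RNAi the median absolute log2 fold change in the authors' deposited table was 1.78 (quartiles 1.32 and 2.76) for higher and 1.64 (1.24 and 2.3) for lower genes (permutation test, p = 0.0178). In overexpression the medians in the authors' deposited table were 1.89 (1.42 and 2.89) and 1.46 (1.22 and 2.01), with a permutation p of 1e-05, the smallest that 100000 permutations give.

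The 2 comparisons listed 179 genes in common, with 194 in RNAi alone and 531 in overexpression alone. Of the 179, 78 were higher in both genotypes and 61 lower in both, and 40 changed in opposite directions. CG14624, CG14866 and CG14892 were lower in both, and in overexpression they were 9.49-, 9.04- and 13.6-fold lower. CG13675, Cpr50Cb, CG12995, CG14752 and CG42326 were higher in both, for instance CG42326 by 22.3-fold in RNAi and 24.1-fold in overexpression. The same direction held for 77.7% of the genes (exact 95% interval 70.8 to 83.5%; Fisher's exact test, p = 2.46e-14). Unchanged groups simulated against the same controls gave 66.5%. The simulated ratios were not selected by size, unlike those of the listed genes, so 66.5% is no baseline for the 77.7%. Across genes, the log2 fold changes of the authors' deposited table correlated with Pearson r = 0.63 and Spearman rho = 0.61 (permutation p = 1e-05 each, the smallest that the permutations can give). Genes are not independent replicates, and neither this test nor that of direction accounts for the shared controls. For log2 ratios of group means the correlation was 0.64, against 0.49 in the simulation, which drew these genes without selecting them anew. The covariance of log2 ratios was 4.23, against 0.053 in the simulation, a difference of 4.17. The simulation already holds the shared controls, but not the selection of the genes against them. The 3 control libraries cannot be split into parts of at least 2. What sharing them adds among the selected genes therefore stays open. Independent lists would share as many genes with 607 genes tested for those lower in both and 1213 for those higher in both. For those lower in RNAi and higher in overexpression the number was 3598, and for the reverse 2774. The 904 genes listed in either comparison exceed the 607; the number tested in both is unknown.

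**Figure D3:**
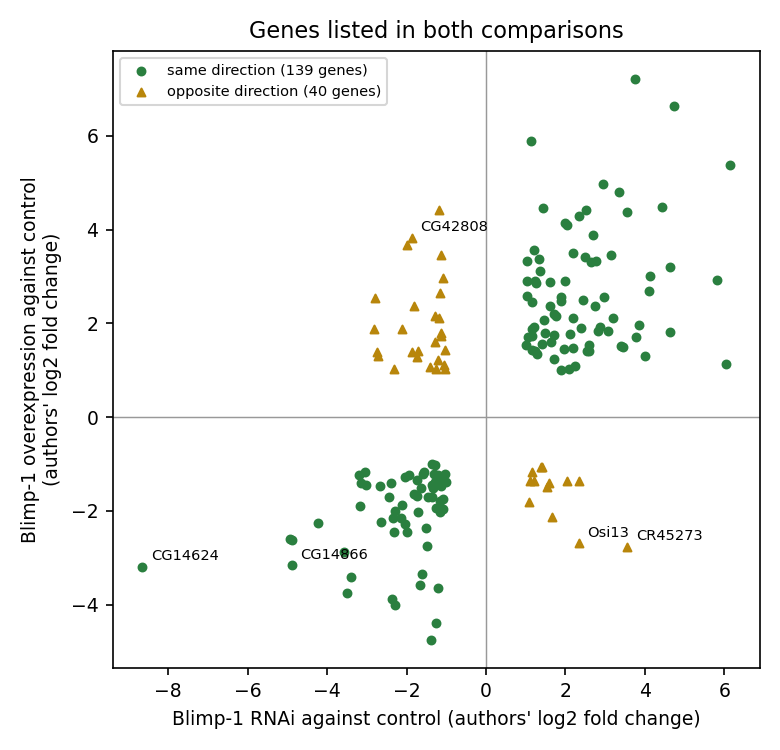
Log2 fold changes of the authors' deposited table for the 179 genes listed in both comparisons, RNAi on the x axis and overexpression on the y axis; each point is a gene. The 139 genes that changed in the same direction lie in the lower left and upper right, and 40 genes lie in the other quadrants.

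Among the 40 genes with opposite directions, 27 were lower in RNAi and higher in overexpression. ImpL1, an ecdysone-inducible gene, was 4.22-fold lower in RNAi and 13.2-fold higher in overexpression, reaching 151516 ± 14739 normalized counts against 11460 ± 3487 in control (SD, n = 3). CG42808 was 3.95-fold lower and 14.7-fold higher, and CG2016, now named Jhbp2, 2.38-fold lower and 22.0-fold higher. CG3339 was 8.16-fold lower and 6.42-fold higher. The other 13 genes were higher in RNAi and lower in overexpression. CR45273 was 12.1-fold higher and 7.82-fold lower (12.3-fold without overexpression replicate 2), and Osi13 5.29-fold higher and 6.85-fold lower. The chitin genes verm, obst-A and Gasp were also in this set, while the chitin genes reb and Idgf6 were higher in both comparisons. In RNAi verm and Gasp were each 2.19-fold higher, and in overexpression verm, obst-A and Gasp were 3.64-, 2.96- and 2.65-fold lower.

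No fixed list passed the test of a different share among the genes listed in RNAi alone and in overexpression alone. The smallest p was 0.159, for the list of noncoding RNA genes taken by symbol, with 5 in RNAi alone and 28 in overexpression alone (Fisher's exact test, adjusted p = 0.883 over 16 lists). Phototransduction genes numbered 2 and 13 (Fisher's exact test, p = 0.377) and synaptic genes 0 and 7 (p = 0.199).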

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

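The refit of recovered reads, the stage, function and site settings, the different control libraries, the library omissions for shared direction and the ratios of means without a library were chosen after the data were seen. Of the alternative values of summary results, 309 stayed the same and 2 did not. Tests counted as the same when they stayed on the same side of the threshold. Gene counts did so within 1.5 times the main count. With a mean of at least 50 normalized counts, the chitin list in overexpression passed the threshold (27.3% of members higher, adjusted p = 0.0363, against 0.0764 without that filter; range 0.0363 to 0.0764), and so did the enzyme class (48 lower, adjusted p = 0.0261 against 0.0502; range 0.0261 to 0.0868); in both cases the cause was not tested. All 1312 alternative values of named genes, from the edgeR refit with all libraries, with a replicate block and without each library, kept direction and threshold. Calls in the edgeR refit without 1 library ranged from 181 to 188 lower and 176 to 184 higher genes in RNAi, and from 187 to 196 lower and 505 to 514 higher in overexpression. The refit starts from genes already selected, and all 373 and 710 genes passed its adjusted p in every setting, so that these values kept their side was fixed by the selection and says nothing about stability. Shared direction could not move when a library was left out, because the groups did not overlap in any of the 189, 184 and 196 genes of the first 3 tables and in 512 of the 514 raised in overexpression. Chance gives 10% for unselected genes, which these are not. A minimum log2 fold change of 1 removed no gene, so its values were the same by construction. Deviations of same-numbered libraries correlated at 0.38, 0.1 and 0.03 in RNAi and 0.5, 0.3 and -0.08 in overexpression. The libraries numbered 1 correlated best with each other in both comparisons, but not every library correlated best with its own number. Whether the libraries numbered 1 shared a batch is not known. With the replicate block the refit called 189 lower and 184 higher genes in RNAi and 196 and 514 in overexpression, the same counts as without it. DESeq2 size factors and a fit with no filter were not run, since they need all genes.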

Other observations

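The tests of chance splits, shared controls, developmental age and a normalization shift were chosen after the results they bear on were seen; those of chromosome arms and neighbouring genes were set out before.

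In overexpression there were 6 runs of at least 4 listed genes in which each gene began within 10000 bp of the end of the listed gene before it. The tetraspanin genes Tsp42Ej, Tsp42Ek, Tsp42El and lbm (2R 7040136 to 7051964) were all 4 higher, as were the glutathione transferase genes GstE1, GstE2, GstE6 and GstE9 (2R 18398393 to 18409835). The other 4 runs held genes of both directions. RNAi had 0 such runs. The hypothesis that listed neighbours share direction was tested over pairs of listed genes that followed each other on an arm within that distance. In RNAi 28 of 40 pairs (70%) shared direction against 49.9% with shuffled directions (permutation test, one-sided, p = 0.00797), and in overexpression 75 of 111 (67.6%) against 59.1% (p = 0.0409). Without overlapping genes the values were 70.3% (permutation p = 0.00989) and 68.9% (permutation p = 0.0244). Tandem copies that share reads or regulation could both give this, and were not separated.

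Genes listed in both comparisons mostly changed the same way although Blimp-1 was targeted by RNAi in one and raised in the other. No fall of Blimp-1 itself was listed in RNAi. Shared control libraries stay open as part of the cause: the covariance of 4.23 lay far above the 0.053 of simulated unchanged groups and was at least 4.09 with different control libraries in 6 assignments, but the genes had been selected against all 3 controls, which the simulation leaves out and which fixes their directions. A single shift in age between control and both genotypes would move early and late genes apart, but among genes that changed the same way in both, 81.5% of the 27 early and 76.1% of the 46 late ones were higher rather than lower, against 30.3% of the 33 that peak at 2 d, which argues against it as the whole cause. Stages for the test of age came from either comparison's tables, and genes with conflicting entries were left out. Linkage to 1 arm is argued against too as the whole cause. The arm with most, 3R, held 29.9% of the genes that changed the same way and 23.4% of the other listed genes. An effect of altered Blimp-1 and a difference in genetic background, since the control carries no UAS insert, stay open and were not tested.

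More genes were higher than lower in overexpression. A uniform normalization shift of otherwise balanced changes would need the same size at every rank, yet it would have to be 0.62 on the log2 scale at the end of the lower list (bootstrap 95% interval 0.56 to 0.7) and 1.33 at rank 20 (0.98 to 1.89). A first form of this test, which set only the 0.62 against fixed bounds, left the question open, and the comparison of ranks replaced it after that was seen. This argues only against a uniform shift of changes that are otherwise alike in both directions. Higher genes also changed more in RNAi, with a median of 1.78 against 1.64, where 184 were higher and 189 lower. A uniform shift of changes unlike in size therefore stays open, as does a smaller shift, because unlisted genes have no values here.

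Only 10 splits of 6 libraries into groups of 3 exist, too few for a share under 0.05. In RNAi the real split called 373 genes in the edgeR refit and the highest other split 0; in overexpression these were 710 and 0, so 1 of 10 splits reached the real count in each. The refit covers genes selected on the real split.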
